A study of Mus musculus with 12 samples.

How the data were processed

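The series held 12 gene expression arrays of embryonic mouse brain tissue in 4 groups of 3. Per the labels, forebrain and midbrain were taken at E11.5 from embryos carrying an inducible mutated YAP1 transgene with a driver active in neural progenitors (TetO-YAP1 with Nes-rtTA) and from control embryos carrying the driver alone, with doxycycline in the food at 200 mg/kg from E7.5. Dorsal telencephalon was taken at E13.5 from embryos with both floxed copies of Nf2 removed by Emx1-Cre and from control embryos with 1 floxed copy and the same Cre, so those controls were heterozygous in the Cre-expressing tissue. The background was mixed. Total RNA was extracted with Trizol, and 100 ng was turned into biotin-labelled cRNA with a 3' IVT Express kit.

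The deposited values were log2 intensities per probe set, given to 2 decimals. The submitters' processing notes name RMA, Affymetrix Expression Console 1.1 and Partek 6.5 without saying what each was used for. The arrays of each experiment looked as if they had been normalized together but separately from the other experiment. Array medians ran from 5.03 to 5.1 in the YAP experiment and from 4.3 to 4.42 in the Nf2 experiment. Levels were therefore not compared across the experiments, only differences from each experiment's own controls, with 1 exception, the scale per day of a globin ratio in the closing section. The median log2 change of all genes was -0.01 for YAP and 0.00 for Nf2. The number of arrays limits the precision of every value.

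The table held 45037 probe sets. Gene names came from the platform table of 2016, which listed 29449 of them, 28898 with a single gene symbol and 551 with several. Of the single-gene probe sets, 28689 were matched to a current symbol through their Entrez ID and 209 were not. Each gene was represented by its probe set with the highest mean over all 12 arrays, which gave 17097 genes. Probe sets tied to no single gene were left out of the gene tests and are reported separately.

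A linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with moderated standard errors (8 residual and 4.096 prior degrees of freedom). The same fit gave the effect of YAP overexpression, the effect of Nf2 knockout and the difference of the 2 effects. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes. A gene was called, and is described as having risen or fallen, at an adjusted p under 0.05. A standard error (SE) beside a log2 change of a single gene comes from this fit, with 3 arrays against 3. The SE beside the mean log2 difference of a list comes from the spread of the list's mean between arrays, without moderation. An exact permutation test of 3 arrays against 3 cannot give a two-sided p below 0.1, so none was used. The pipeline was tested on simulated data with 200 changed genes in 10 simulations. It recovered 59.0% of genes changed by 0.5 on the log2 scale and 96.1% of those changed by 1 in the YAP experiment, 59.3% and 94.0% in the Nf2 experiment, and 4.67% and 5.23% of the calls were false. The simulated noise was normal and independent between genes and arrays, without pairs, so these shares may not carry over to the real arrays.

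Labels number the arrays of each group but do not say that they came from separate embryos. Each group held arrays of both sexes by Xist and Y-linked transcripts, so more than 1 embryo, but whether all 3 were separate is not known, and the p-values measure the spread between these samples, which may be technical in part. Whether equal numbers pair arrays was tested with the correlation of their residuals. In the Nf2 experiment the 3 correlations were 0.271, 0.212 and 0.207, against a highest value of -0.000108 among arrays with unequal numbers. The Nf2 counts are therefore also given with replicate number as a block. In the YAP experiment they were 0.0971, -0.195 and -0.204, which did not point to pairs.

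There were 24 gene lists with 343 distinct genes, 318 of them measured. They covered YAP/TEAD target genes, Hippo pathway components, radial glia and apical progenitors, intermediate progenitors and neurogenic commitment, postmitotic neurons, G1/S and DNA replication, G2/M and mitosis, p53 response and apoptosis, the Notch pathway, actin cytoskeleton and focal adhesion, cortical hem and dorsal midline, choroid plexus epithelium, ventral telencephalon and GABAergic neurons, midbrain and diencephalon, hindbrain, glial lineage, endothelium, mesenchyme and pericytes, microglia and macrophages, erythroid cells, surface ectoderm and epithelium, hypoxia and glycolysis, immediate early genes, and sex-linked transcripts. The remaining list genes were matched to no single-gene probe set and were not analysed here. Each list was compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 24 lists within a comparison. Camera with an estimated correlation was run as an alternative. Fry was run too, which tests another hypothesis, whether a list's genes move on balance one way, and does not compare the list with other genes.

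The genes named were Yap1 and Nf2 on every probe set, the 10 rising and 10 falling called genes with the largest log2 change whose arrays did not overlap between groups, up to 4 called members of each list by smallest p and every member of the YAP/TEAD list, and the 10 genes called in the same direction in both comparisons with the largest smaller change. Predicted genes and unnamed transcripts were counted but not named. The lists, this rule, the comparisons, the threshold, the tests and the alternatives were chosen before the data were examined, except where a test or alternative is said to have been chosen later.

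The alternatives were the replicate block, a fit on the 6 arrays of a comparison, leaving out the dimmest 40% of genes, the mean of a gene's probe sets, leaving out probe sets with the suffix _x_at or _s_at, quantile normalization over all arrays, median subtraction, trended and robust moderation, array weights, each array left out in turn, stricter and looser thresholds, all probe sets as the unit of test, the other set tests and the YAP/TEAD list without Ankrd1, Ccn1 and Ccn2. Quantile normalization within each experiment and embryo sex as a covariate were chosen after seeing the data. The arrays' raw intensities were not used here.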

Results

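RNA from embryonic mouse brain was measured on 12 arrays, 3 in each of 4 groups. In the first experiment, forebrain and midbrain at E11.5 came from embryos in which neural progenitors carried a doxycycline-inducible, mutated YAP1 (YAP overexpression) or only the driver of that transgene (YAP control). YAP is a transcriptional co-activator that the Hippo pathway inhibits. In the second, dorsal telencephalon at E13.5 came from embryos lacking Nf2 in the cells expressing Emx1-Cre (Nf2 knockout) or keeping 1 copy there (Nf2 control). Nf2 encodes Merlin, which acts upstream of the Hippo kinases. The arrays gave a value for 17097 genes. Within a group, arrays correlated with r of at least 0.993 across genes, and their number limits the precision.

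The manipulated genes themselves were not called. Yap1 averaged 11.04 (SD 0.04, n = 3) in YAP controls and 11.30 (SD 0.06, n = 3) with overexpression. The single arrays read 11.07, 10.99 and 11.05 against 11.35, 11.23 and 11.33. This log2 difference of 0.27 (SE 0.07) was 1.2-fold and was not called (adjusted p = 0.0551). Whether the Yap1 probes match the transgene is not known here. Nf2 averaged 8.53 (SD 0.13, n = 3) in Nf2 controls, with arrays at 8.41, 8.66 and 8.51, and 8.15 (SD 0.11, n = 3) in knockouts, with arrays at 8.06, 8.27 and 8.11. This difference of -0.38 (SE 0.09) was not called either (adjusted p = 0.246). Within the same-numbered pairs Nf2 differed by -0.35, -0.39 and -0.40, and with the block it was again not called (adjusted p = 0.241), with an unadjusted p of 0.00136. All 4 Nf2 probe sets were lower in the knockouts, by between -0.38 and -0.09, and they may lie outside the deleted part of the gene. Those other than the brightest had an unadjusted limma p from 0.0831 to 0.356. In the YAP experiment, where Nf2 was not manipulated, all 4 were lower as well, by between -0.22 and -0.04, so their shared sign does not show the deletion. Nf2 in the YAP experiment (-0.05, adjusted p = 0.837) and Yap1 in the Nf2 experiment (-0.01, adjusted p = 0.994) were not called.

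The first comparison asked which genes change when YAP is overexpressed in the early brain. Of the listed genes, 6 of 20 YAP/TEAD targets and 7 of 21 Hippo components rose, and 11 of 13 genes of intermediate progenitors, 14 of 21 of neurons and 9 of 10 of the ventral telencephalon fell, though none of these lists was called as a set with an estimated correlation (adjusted p from 0.105 to 0.14). Fry, which does not compare a list with other genes, called each of them in the same direction (adjusted p from 0.000186 to 0.00457). Ccn2 and Ccn1, which encode secreted matrix-associated proteins often used as YAP reporters, rose 5.67-fold (log2 2.50, SE 0.22) and 3.82-fold (log2 1.93, SE 0.11), with 3 arrays against 3. Dlx1 and Dlx2, homeobox genes of GABAergic neuron development, fell by 2.19 (SE 0.38) and 1.92 (SE 0.22) on the log2 scale. Eomes, the marker of cortical intermediate progenitors, and Tbr1, a transcription factor of early cortical neurons, fell by 1.22 (SE 0.10) and 1.49 (SE 0.25). The adjusted p was 7.1e-05 for Ccn2, 1.89e-06 for Ccn1, 0.00551 for Dlx1, 0.000465 for Dlx2, 3.21e-05 for Eomes and 0.00477 for Tbr1.

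In total 1078 genes were called, 456 higher and 622 lower, and 446 of them changed at least 1.5-fold. At least 2-fold changes were seen in 56 rising and 49 falling genes. Over all genes the arrays of the groups did not overlap in 21.3% (3636 genes), where chance gives 10%, and the called genes, which the test favours for such separation, included 1075 of these. Higher genes made up 42.3% of the calls, but 52.8% (528 against 472 lower) once each array's median was subtracted, so the balance of the directions depended on the scaling. The count fell to 688 without overexpression replicate 1, 678 without replicate 3, 674 without control replicate 1, 529 without control replicate 3, and 361 when only these 6 arrays were fitted.

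The largest rise was that of Clu, a secreted chaperone, at 12.2-fold (log2 3.60, SE 0.21), and its 3 probe sets ranged from 2.83 to 3.60. Steap1, a transmembrane protein gene, rose 8.15-fold (log2 3.03, SE 0.16), and Pkp2, a plakophilin of cell junctions, 6.51-fold (log2 2.70, SE 0.11). Apela, a peptide ligand of the apelin receptor, rose by 2.11 (SE 0.13) on 1 probe set while its other probe set differed by 0.12. Next came Tuft1 (2.03, SE 0.23), the phosphatase gene Dusp3 (1.98, SE 0.08), Ajuba, whose LIM protein binds LATS kinases (1.86, SE 0.15) and the glucose transporter gene Slc2a3 (1.74, SE 0.11). The adjusted p values of these 8 genes ran from 1.12e-07 to 0.000401. With the _x_at and _s_at probe sets left out, Slc2a3 turned to -0.18 (adjusted p = 0.353) and Pkp2 was no longer called (0.14, adjusted p = 0.536). The probe sets of the called genes Lats2, Arhgef17, Wwc1, Pax6, Trp53inp1, Nfib, Nfia and Adamts9 also differed in sign.

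Among the 10 largest falls were further genes of the ventral forebrain and of neurons. Dlx6os1, a noncoding transcript of the Dlx5 and Dlx6 locus, fell by 1.98 (SE 0.26), Dlx5 by 1.87 (SE 0.29), and Lhx8, a homeobox gene of the basal forebrain, by 1.84 (SE 0.36). Gad1, the enzyme that makes GABA, fell by 1.83 (SE 0.19). Lhx1 fell by 1.75 (SE 0.38), St18 by 1.56 (SE 0.14), and the glutamate receptor gene Gria2 by 1.48 (SE 0.39). Their adjusted p ranged from 7.36e-05 to 0.043.

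Of the 20 measured YAP/TEAD target genes, 6 rose, none fell (2 were lower at an unadjusted p under 0.05) and 14 were not called (camera adjusted p = 0.00192, higher). Adjusted over the list alone, 8 were higher and 1 lower. Besides Ccn1 and Ccn2, the rising members were Ptpn14, a phosphatase that binds YAP (1.66, SE 0.18), the angiomotin family gene Amotl2 (0.73, SE 0.08), Lats2, a kinase of the Hippo pathway (0.97, SE 0.20), and Arhgef17 (0.52, SE 0.13). Igfbp3 (0.66, adjusted p = 0.057), F3 (0.59, adjusted p = 0.0844), Ankrd1 (0.41, adjusted p = 0.206) and Gadd45a (-0.36, adjusted p = 0.101) were not called. Nor were Tgfb2, Crim1, Dock5, Asap1, Nt5e, Rbms3, Foxf2, Myof, Fjx1 and Ccdc80, with differences from -0.36 to 0.25, so 10 members had a positive and 10 a negative difference. The list's call was lost with an estimated correlation (adjusted p = 0.136) and without Ankrd1, Ccn1 and Ccn2 (adjusted p = 0.135), while it was kept with any 1 array left out (0.000157 to 0.0135). Fry, which does not compare a list with other genes, called it higher (adjusted p = 0.000829).

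Among 21 Hippo pathway components, which share Lats2 and Amotl2 with the target list, 7 rose, none fell (1 was lower at an unadjusted p under 0.05) and 14 were not called, with 8 higher adjusted over the list alone (camera adjusted p = 0.000104, and adjusted p = 0.106 with an estimated correlation). The scaffold genes Wwc2 (1.02, SE 0.10) and Wwc1 (0.84, SE 0.13) rose, as did Tead1, a DNA-binding partner of YAP (0.55, SE 0.07). Among 22 genes of the actin cytoskeleton and focal adhesion, 3 rose, none fell and 19 were not called, with 9 higher adjusted over the list alone (camera adjusted p = 4.53e-06, and adjusted p = 0.14 with an estimated correlation). The 3 were the tropomyosin gene Tpm1 (1.26, SE 0.12), the vinculin gene Vcl (0.64, SE 0.11) and the actinin gene Actn1 (0.34, SE 0.09).

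Intermediate progenitor and neurogenic commitment genes fell in 11 of 13 cases and none rose, both over all genes and adjusted over the list alone (camera adjusted p = 3.35e-15, and adjusted p = 0.105 with an estimated correlation). They included Sstr2, a somatostatin receptor gene (-1.01, SE 0.07), Mfng, a glycosyltransferase acting on Notch (-1.0, SE 0.10), and Gadd45g (-0.62, SE 0.09). Of 21 genes of postmitotic neurons, 14 fell, none rose and 7 were not called, with 18 lower adjusted over the list alone (camera adjusted p = 2.23e-15, and adjusted p = 0.14 with an estimated correlation). Examples were the neuronal RNA-binding protein gene Elavl4 (-0.82, SE 0.08), the transcription factor gene Neurod1 (-0.90, SE 0.13), the calretinin gene Calb2 (-0.76, SE 0.11), and the vesicular glutamate transporter gene Slc17a6 (-1.02, SE 0.15). Of 10 genes of the ventral telencephalon and GABAergic neurons, 9 fell, none rose and 1 was not called, likewise adjusted over the list alone (camera adjusted p = 8.08e-12, and adjusted p = 0.106 with an estimated correlation). The mean log2 difference was -0.67 (SE 0.10) for the intermediate progenitor list, -0.70 (SE 0.20) for neurons and -1.26 (SE 0.20) for the ventral telencephalon.

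Genes of radial glia and apical progenitors went both ways. Of 20, 3 rose, 5 fell and 12 were not called, with 3 higher and 6 lower adjusted over the list alone. The Notch effector gene Hes1 rose (0.60, SE 0.10), and the cortical transcription factor genes Lhx2 (-0.69, SE 0.08), Emx2 (-0.68, SE 0.10) and Pax6 (-0.34, SE 0.07) fell. This list's median was 0.06, its mean -0.07, and the test pointed lower without a call (camera adjusted p = 0.808). In the Notch pathway list, 1 of 14 genes rose, 4 fell and 9 were not called, the same counts as adjusted over the list alone (camera adjusted p = 0.0466, lower, and adjusted p = 0.445 with an estimated correlation). The falling genes included Hey1 (-0.67, SE 0.09), Nrarp (-0.52, SE 0.07), both induced by Notch signalling, and the Notch ligand gene Dll1 (-0.58, SE 0.09). The Notch list's adjusted p was 0.0652 without control replicate 1, 0.105 without control replicate 3, 0.0527 without overexpression replicate 1 and 0.105 without replicate 3.

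Hypoxia and glycolysis genes rose in 6 of 11 cases and none fell, also adjusted over the list alone (camera adjusted p = 7.24e-06, and adjusted p = 0.149 with an estimated correlation). Egln3, an oxygen-sensing hydroxylase gene (0.87, SE 0.12), Bnip3, which acts in mitophagy (0.91, SE 0.14), the lactate dehydrogenase gene Ldha (0.41) and the glucose transporter gene Slc2a1 (0.43) were among them. Of 14 genes of the p53 response and apoptosis, 2 rose, 1 fell and 11 were not called, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0193, higher, and adjusted p = 0.474 with an estimated correlation). Phlda3 (1.13, SE 0.25) and Ccng1 (0.83, SE 0.21) rose and Trp53inp1 fell (-0.45, SE 0.10). Without overexpression replicate 2 the p53 list was not called (adjusted p = 0.247). Of 10 immediate early genes, 2 rose, 1 fell and 7 were not called, with 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.135). These were the stress-induced Atf3, which rose 2.83-fold (log2 SE 0.15), Jun (0.43) and the antiproliferative gene Btg2 (-0.72, SE 0.12).

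The following lists of other regions and cell types held some called genes, and camera called none of them. Over all genes, 1078 of 17097 were called. Among 13 genes of the cortical hem and dorsal midline, Bmp6 (1.34, SE 0.15) and Wnt5a (0.75, SE 0.12), which encode secreted signals, rose, and Rspo1, a secreted activator of Wnt signalling, fell (-0.52, SE 0.13), with 10 not called and the same counts adjusted over the list alone (camera adjusted p = 0.582). Of 9 choroid plexus genes, the folate receptor gene Folr1 rose 2.82-fold (log2 SE 0.14) and 8 were not called, also adjusted over the list alone (camera adjusted p = 0.191). Of 13 midbrain and diencephalon genes, Th, which makes the precursor of dopamine, fell (-0.72, SE 0.13), with 12 not called and 4 lower adjusted over the list alone (camera adjusted p = 0.131). Of 9 hindbrain genes, the homeobox gene Gbx2 fell (-0.68, SE 0.13), with 8 not called, and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.998). Of 14 glial genes, 4 fell and 10 were not called, also adjusted over the list alone (camera adjusted p = 0.0859). These were Nfia (-0.91) and Nfib (-0.84), transcription factor genes of gliogenesis, Olig2 (-0.73), which specifies oligodendrocytes, and Sparcl1 (-0.51). The glial list's mean differed by -0.24 (SE 0.08), its groups did not overlap, and fry called it lower (adjusted p = 0.0396). Of 10 genes of surface ectoderm and epithelium, the keratin gene Krt19 rose (0.84, SE 0.11) and 9 were not called, also adjusted over the list alone (camera adjusted p = 0.808). That list's median was -0.07 and its mean 0.01.

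Limma called no gene of 7 further lists in this comparison, over all genes or adjusted over the list alone. An unadjusted p under 0.05 was found for 2 of 19 G1/S and DNA replication genes (camera adjusted p = 0.0926), 1 of 17 G2/M and mitosis genes (0.808), 0 of 12 endothelial genes (0.673), 3 of 11 genes of mesenchyme and pericytes (0.0859), 0 of 10 microglial genes (0.664), 2 of 9 erythroid genes (0.135) and 0 of 4 sex-linked transcripts (0.998). Some of these lists, and the midbrain list described before them, were called by camera with 1 array left out. The G1/S list reached 0.0162, higher, and the midbrain list 0.0244, lower, without overexpression replicate 2, the mesenchymal list 0.000133, lower, without control replicate 3 and 0.0451 without overexpression replicate 3, and the erythroid list 0.00292, lower, without overexpression replicate 3. Of the 72 called genes the rule named, 18 were not called with 1 of the 6 arrays left out, namely Actn1, Arhgef17, Ccng1, Fgd5, Gria2, Jun, Lats2, Ldha, Lhx1, Nfia, Nfib, Olig2, Pax6, Phlda3, Rspo1, Slc2a1, Sparcl1 and Trp53inp1. By array they were 11 without control replicate 1, 9 without control replicate 2, 15 without control replicate 3, 14 without overexpression replicate 1, 4 without replicate 2 and 8 without replicate 3.

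**Figure D1:**
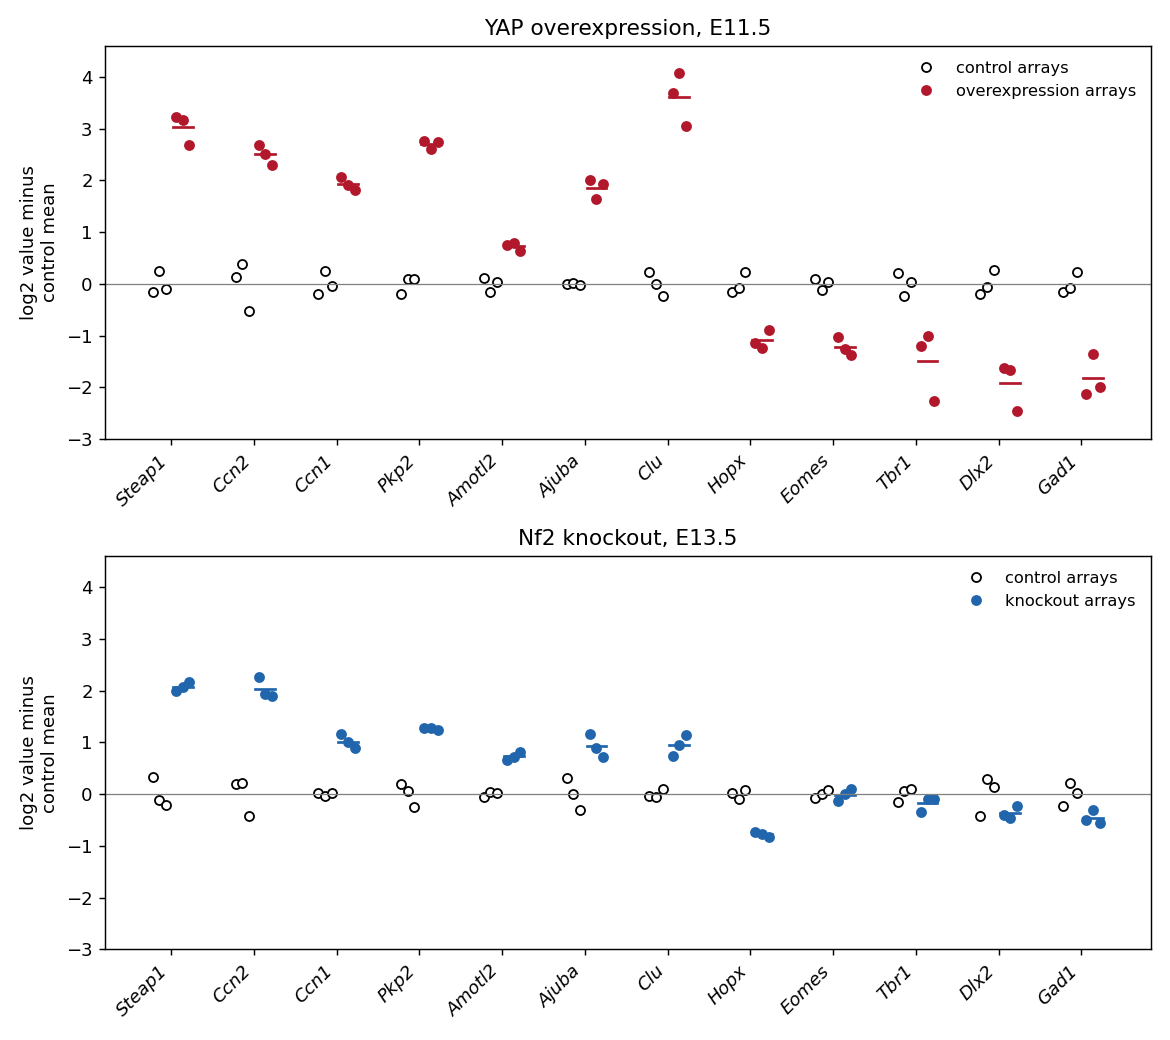
Log2 value of 12 named genes on each array minus the mean of that experiment's controls, with YAP arrays and Nf2 arrays in separate panels, a point per array and a bar at the mean of the treated group. Ccn2 averages 2.50 above controls in the YAP panel and 2.03 in the Nf2 panel, while Eomes and Dlx2 lie below controls on every YAP overexpression array.

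The second comparison asked which genes change in the dorsal telencephalon when Nf2 is lost, against controls with 1 copy. Fewer genes were called than with YAP overexpression, and most of them rose. Steap1 rose 4.22-fold (log2 2.08, SE 0.16), Ccn2 4.09-fold (log2 2.03, SE 0.22) and Ccn1 2.02-fold (log2 1.02, SE 0.11), with 3 arrays against 3. Hopx, a small homeodomain protein gene, fell by 0.78 (SE 0.11) on the log2 scale. No gene of the neuronal, intermediate progenitor or ventral telencephalic lists passed limma's test, and 1, 1 and 2 of their genes had an unadjusted p under 0.05. The adjusted p was 0.000445 for Steap1, 0.00165 for Ccn2 and Ccn1 and 0.0101 for Hopx.

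In total 43 genes were called, 35 higher and 8 lower, against 1066 at an unadjusted p under 0.05. Over all genes the arrays of the groups did not overlap in 12.7% (2170 genes), where chance gives 10%, and the 43 called genes, which the test favours for such separation, were all among these. At least 1.5-fold changes were seen in 32, and at least 2-fold changes in 9, all higher. With same-numbered arrays as a block the count was 21, 19 of them among the 43, with only these 6 arrays 25, and with array weights 67. Higher genes made up 81.4% of the calls, and 91.7% after quantile normalization. Leaving out control replicate 2 gave 25 genes, control replicate 3 gave 23 and knockout replicate 2 gave 20.

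Other large rises were those of Pkp2 (1.26, SE 0.11), Plekhb1 (1.25, SE 0.18), Casq1, which binds calcium in muscle (1.25, SE 0.12), Fgfbp3, which binds fibroblast growth factors (1.15, SE 0.17), Pdlim1, an actin-associated LIM protein gene (1.11, SE 0.11), and Cckar, a cholecystokinin receptor gene (0.98, SE 0.10). The other genes that fell were Vstm2a (-0.85, SE 0.14), Mettl23 (-0.81, SE 0.13), the neuronal pentraxin gene Nptx2 (-0.66, SE 0.11), Fgd5 (-0.63, SE 0.10), the cyclic AMP phosphodiesterase gene Pde4a (-0.49, SE 0.09), Nkain2 (-0.48, SE 0.08) and the metalloprotease gene Adamts9 (-0.43, SE 0.07). The adjusted p of these genes ran from 0.00075 to 0.0366. Pkp2 was not called with the _x_at and _s_at probe sets left out (0.01, adjusted p = 0.994), and the probe sets of Adamts9 and Wwc2 differed in sign. Taking the mean of a gene's probe sets ended the calls of Hopx, Dusp3, Adamts9, Nkain2 and Nptx2. With the block the calls ended for Wwc2, Egln3, Plekhb1, Fgfbp3, Vstm2a, Mettl23, Nptx2, Fgd5, Pde4a, Nkain2 and Adamts9, whose adjusted p ran from 0.0519 to 0.186. Of the 24 called genes the rule named, 13 were not called with 1 array left out, namely Adamts9, Ajuba, Dusp3, Fgd5, Fgfbp3, Hopx, Mettl23, Nkain2, Nptx2, Pde4a, Plekhb1, Vstm2a and Wwc2. By array they were 4, 7 and 11 without control replicates 1, 2 and 3, and 6, 11 and 8 without knockout replicates 1, 2 and 3.

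Of the 20 YAP/TEAD target genes, 3 rose, none fell (2 were lower at an unadjusted p under 0.05) and 17 were not called. These were Ccn1, Ccn2 and Amotl2 (0.73, SE 0.08, adjusted p = 0.00231), and adjusted over the list alone 4 were higher and 1 lower. The uncalled members ran from -0.34 for Igfbp3 to 0.66 for Ptpn14 (adjusted p = 0.353). Camera called the list higher (adjusted p = 0.0161). The call was lost with an estimated correlation (adjusted p = 0.242) and without Ankrd1, Ccn1 and Ccn2 (adjusted p = 0.453), while it was kept with any 1 array left out (0.00917 to 0.0339). Fry, which does not compare a list with other genes, did not call it (adjusted p = 0.121). Of 21 Hippo pathway components, Amotl2 and Wwc2 (0.70, adjusted p = 0.00974) rose, none fell and 19 were not called, with 2 higher and 1 lower adjusted over the list alone. That list was called higher (camera adjusted p = 0.0168, and adjusted p = 0.29 with an estimated correlation), but not without control replicate 2 (0.107) or knockout replicate 1 (0.0937), and within pairs its mean differences were 0.115, 0.147 and 0.014, with a call under the block (adjusted p = 0.0371). Of 22 actin cytoskeleton and focal adhesion genes, Tpm1 rose (1.04, SE 0.12) and 21 were not called, also adjusted over the list alone (camera adjusted p = 6.54e-05, higher, and adjusted p = 0.242 with an estimated correlation). Of 11 hypoxia and glycolysis genes, Egln3 rose (0.95, adjusted p = 0.00553) and 10 were not called, also adjusted over the list alone (camera adjusted p = 0.000688, higher, and adjusted p = 0.291 with an estimated correlation).

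Limma called no gene of the other 20 lists over all genes, but camera called 9 of them on small shifts shared by many members. All 21 measured neuronal genes had a negative difference, with a mean of -0.16 (SE 0.07), groups that overlapped, and 1 at an unadjusted p under 0.05 and none called adjusted over the list alone (camera adjusted p = 0.000688, and adjusted p = 0.442 with an estimated correlation). That call ended without knockout replicate 1 (0.0594), but within the same-numbered pairs the mean differences were -0.159, -0.158 and -0.157, and the list was called with the block (adjusted p = 0.0024). All 10 ventral telencephalic genes had a negative difference, with a mean of -0.30 (SE 0.17), groups that overlapped, and 2 at an unadjusted p under 0.05 and none called adjusted over the list alone (camera adjusted p = 0.000688, and adjusted p = 0.304 with an estimated correlation). Without control replicate 2 this call ended as well (0.0695), and the mean differences within pairs were -0.079, -0.545 and -0.289, with a call under the block (adjusted p = 0.000893). Of 20 radial glial genes, 14 were higher, with 4 at an unadjusted p under 0.05 and 1 higher adjusted over the list alone (camera adjusted p = 0.0168, and adjusted p = 0.331 with an estimated correlation). It was not called without control replicate 2 (0.071), control replicate 3 (0.0616), knockout replicate 1 (0.0608) or knockout replicate 2 (0.0624), while the mean differences within pairs were 0.050, 0.093 and 0.028 and the list was called with the block (adjusted p = 0.0414). In the intermediate progenitor list 1 of 13 genes had an unadjusted p under 0.05 and none was called adjusted over the list alone (camera adjusted p = 0.651). Its median was 0.01, its mean -0.01 and the test pointed lower.

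Of 19 G1/S and DNA replication genes 16 had a positive difference, with a mean of 0.10 (SE 0.06) over the list and with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.000106, and adjusted p = 0.291 with an estimated correlation). Of 17 G2/M and mitosis genes 15 had a positive difference, with a mean of 0.07 (SE 0.05) and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.00608, and adjusted p = 0.442 with an estimated correlation). The list means of the groups overlapped for both. Limma called none of either list adjusted over the list alone, and the G2/M call ended without control replicate 3 (0.136) or knockout replicate 1 (0.155). Within the same-numbered pairs the mean differences were 0.129, 0.078 and 0.105 for G1/S and 0.072, 0.067 and 0.081 for G2/M, and both lists were called with the block (adjusted p = 0.000126 and 0.0116). Of 13 cortical hem and dorsal midline genes 11 had a positive difference, with a mean of 0.22 (SE 0.12), groups that overlapped, and 5 at an unadjusted p under 0.05 and 2 higher adjusted over the list alone (camera adjusted p = 6.54e-05, and adjusted p = 0.242 with an estimated correlation).

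Of 10 microglial and macrophage genes 9 were higher, by a mean of 0.26 (SE 0.03, n = 3), with 3 at an unadjusted p under 0.05 and 1 higher adjusted over the list alone. This was the only list of this comparison whose call held with an estimated correlation (camera adjusted p = 9.4e-05, and adjusted p = 0.0474 with an estimated correlation). Its estimated correlation was -0.00813, below the preset 0.01, yet its unadjusted camera p rose from 1.567e-05 to 0.001975. The 2 ways of running camera thus differ in more than the correlation, and a call lost with an estimated correlation need not be lost through the correlation alone. All 12 endothelial genes were lower, by a mean of -0.28 (SE 0.14, n = 3), with 5 at an unadjusted p under 0.05 and none called adjusted over the list alone (camera adjusted p = 2.96e-05, and adjusted p = 0.242 with an estimated correlation). The endothelial mean was -0.16 (SE 0.11) without knockout replicate 3, and the groups overlapped, with knockout replicate 1 at -0.056 and control replicate 1 at -0.059 from the control mean. Of 9 erythroid genes 6 were lower, by a mean of -0.26 (SE 0.05, n = 3), with 4 at an unadjusted p under 0.05 and 4 lower adjusted over the list alone (camera adjusted p = 9.56e-05, and adjusted p = 0.242 with an estimated correlation).

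Camera did not call the remaining lists, and no gene in them was called by limma, also adjusted over the list alone. An unadjusted p under 0.05 was found for 0 of 14 genes of the p53 response and apoptosis (camera adjusted p = 0.398), 2 of 14 Notch pathway genes (0.297), 1 of 9 choroid plexus genes (0.239), 2 of 13 midbrain and diencephalon genes (0.239), 1 of 9 hindbrain genes (0.295), 4 of 14 glial genes (0.311), 1 of 11 genes of mesenchyme and pericytes (0.0914), 1 of 10 genes of surface ectoderm and epithelium (0.344), 0 of 10 immediate early genes (0.297) and 0 of 4 sex-linked transcripts (0.453). With 1 array left out, the choroid plexus list was called lower without knockout replicate 2 (0.021), the glial list without control replicate 1 (0.0412) and the mesenchymal list without knockout replicate 1 (0.0173).

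**Figure D2:**
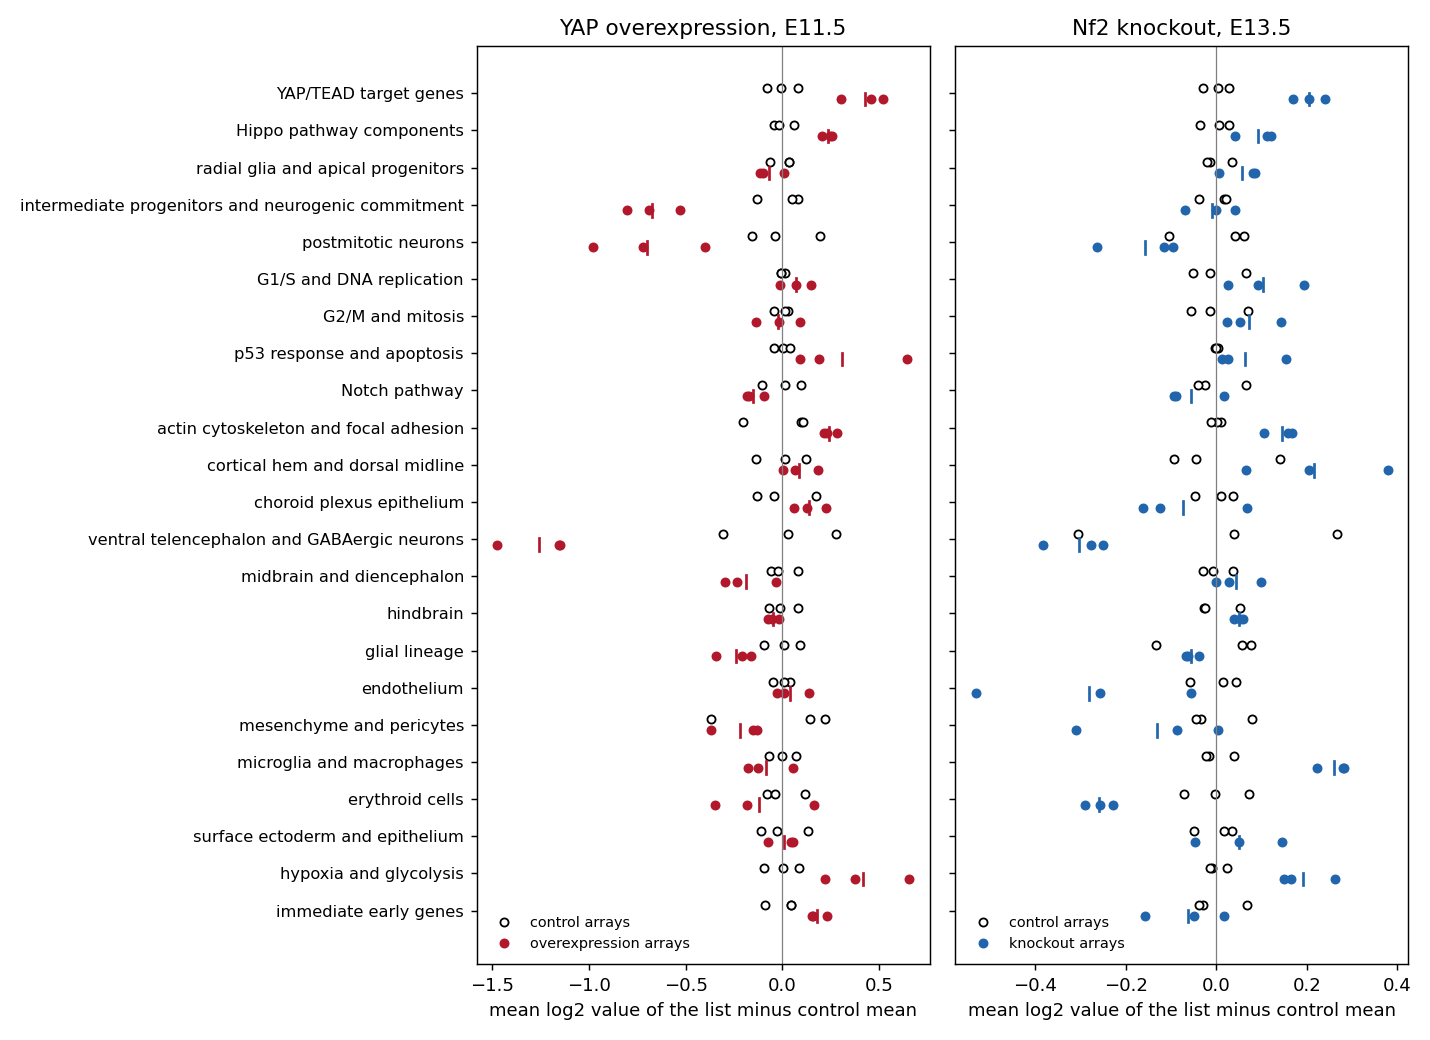
Mean log2 value of 23 gene lists on each array minus the mean of that experiment's controls, with a point per array and separate panels, on different scales, for the YAP and the Nf2 experiment. The ventral telencephalic list averages -1.26 with YAP overexpression, and the microglial list lies 0.22 to 0.28 above controls on the Nf2 knockout arrays.

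The third comparison asked which genes change in both experiments, since Merlin acts upstream of YAP. Both raised 26 genes, against 0.933 if the calls were independent, and both lowered 2, Hopx and Fgd5, against 0.291. The shared fit uses the same estimate of a gene's spread for both comparisons, which ties the calls to one another, so these reference counts may be too low. The shared rising genes were led by Steap1 (3.03 with YAP overexpression and 2.08 in Nf2 knockout) and Ccn2 (2.50 and 2.03). Next were Pkp2 (2.70 and 1.26), Fgfbp3 (1.31 and 1.15), Pdlim1 (1.60 and 1.11), Tpm1 (1.26 and 1.04), Ccn1 (1.93 and 1.02), Cldn12, a claudin gene of cell junctions (1.30 and 0.96), and Ajuba (1.86 and 0.92). Egln3 completed the first 10 (0.87 and 0.95). Hopx fell in both (-1.09 and -0.78), as did Fgd5 (-0.44 and -0.63). With the mean of its probe sets Hopx was called in neither comparison, and Fgd5 lost both calls with the block. Adamts9 rose with YAP overexpression (0.52, adjusted p = 0.000837) and fell in Nf2 knockout (-0.43, adjusted p = 0.0158). Its Nf2 call ended with the block (adjusted p = 0.118), and with the mean of its probe sets it was called in neither comparison. Also opposite was 1 other gene, Nxt2, which was chosen after its values were seen. Nxt2 fell with YAP overexpression (-0.30) and rose in Nf2 knockout (0.45), where its call ended with the block (adjusted p = 0.131).

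Of the 43 genes called in Nf2 knockout, 13 were not called with YAP overexpression. The 28 genes that changed alike in both were 15 with the block, 18 when only the 6 arrays of each comparison were fitted, and 44 with trended and robust moderation, and the count was 17 without Nf2 control replicate 2, 17 without Nf2 control replicate 3 and 15 without Nf2 knockout replicate 2. Across all genes the effects correlated with Pearson's r = 0.332 and a Spearman rank correlation of 0.241, and 57.9% of genes had the same sign. Across the 1091 genes called in either comparison Pearson's r was 0.641 and the Spearman rank correlation 0.639, with the same sign in 81.1%. Genes are not independent replicates, so no p is given for these.

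**Figure D3:**
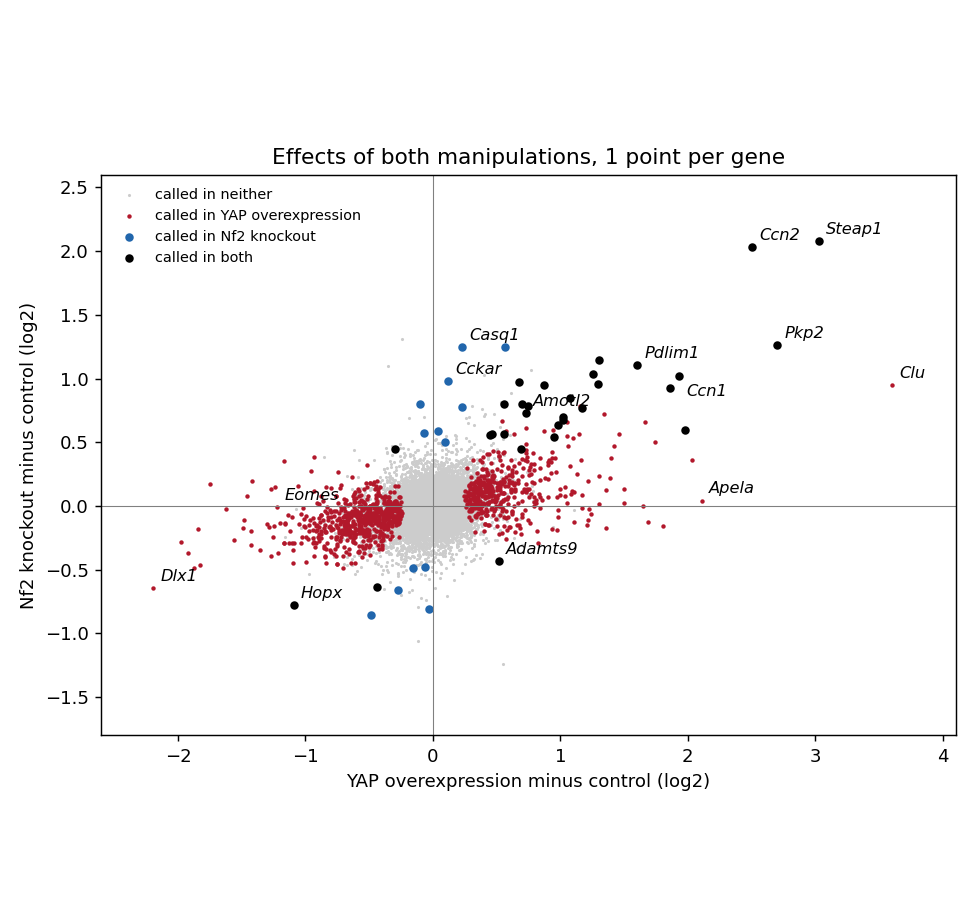
Log2 effect of Nf2 knockout against log2 effect of YAP overexpression, with a point per gene (the sex-linked Xist, Eif2s3y, Kdm5d and Uty are left out). Steap1 and Ccn2 stand apart at the upper right, above 2 on both axes, while Clu lies at 3.60 for YAP overexpression and 0.95 for Nf2 knockout.

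The fourth comparison asked where the effects differed, by a test of the difference within the same fit. It called 48 genes, 29 with a higher and 19 with a lower effect in YAP overexpression than in Nf2 knockout, and 21 with the block. Clu differed by 2.66, Apela by 2.07, Eomes by -1.21 and St18 by -1.30 on the log2 scale. Apela read only 3.20 to 3.47 on the Nf2 arrays, below their medians of 4.3 to 4.42, so a change there may go unseen. Among the shared rising genes, the rise was larger with YAP overexpression in 17 and in Nf2 knockout in 9, with medians of 1.02 and 0.80. The difference was called for 3 of them, Pkp2 (adjusted p = 0.00274), Ccn1 (adjusted p = 0.0333) and Dusp3 (adjusted p = 0.00027). Pkp2 read below the array median on every Nf2 control array, so its rise there may be understated and its difference overstated. By list, the effects of YAP overexpression were lower than those of Nf2 knockout for intermediate progenitors (camera adjusted p = 2.71e-16), neurons (7.02e-11), the ventral telencephalon (1.44e-08), microglia (0.0052) and the midbrain (0.0202). They were higher for endothelium (0.0017), Hippo components (0.0104), YAP/TEAD targets (0.0202), hypoxia and glycolysis (0.0202), immediate early genes (0.0241) and choroid plexus (0.0247). None of these list differences held with an estimated correlation (adjusted p from 0.0817 to 0.443). The experiments also differed in age, tissue and genotype of the controls, which the test cannot part from the manipulated gene. The number of differing genes was 161 without YAP overexpression replicate 2 and between 21 and 29 without YAP overexpression replicate 1, YAP control replicate 1 or 3, any Nf2 control replicate, or Nf2 knockout replicate 1 or 3.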

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

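The tests of ventral telencephalon, of telencephalon against midbrain, of vessel and blood, of sex and of single arrays for the erythroid and microglial lists, and of a compressed scale were chosen only after the results were seen. With 3 arrays in a group, no formal test for outlying samples was made. The influence of single arrays was read only from array weights and from leaving each array out in turn.

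With YAP overexpression, camera called the lists of neurons, intermediate progenitors and ventral telencephalon lower, and lower than in Nf2 knockout, but with an estimated correlation neither these calls (adjusted p = 0.14, 0.105 and 0.106) nor the differences (0.22, 0.0817 and 0.191) held. Fry, which does not compare a list with other genes, called each of these lists lower with YAP overexpression (adjusted p = 0.00457, 0.000186 and 0.000829). For the difference, fry called only intermediate progenitors (adjusted p = 0.106, 0.00292 and 0.0554). Younger transgenic embryos may lower such genes and stay open, since the upper 95% bound of a delay, 0.43 day by the ratio of embryonic to definitive globins, takes its scale per day from YAP controls against Nf2 controls, which differ in tissue and look separately normalized. Less ventral telencephalon in the dissections would not lower genes of cortical excitatory neurons and their precursors. These were lower too, with a median of -0.88, a mean of -0.80 (SE 0.17) and 6 of 9 called lower. All 9 belong to the neuronal and intermediate progenitor lists, already seen to be lower, so they are no independent test. They do not bear on the ventral genes themselves, for which less ventral tissue stays open. Less telencephalon relative to midbrain would lower genes of telencephalic neurons only, while neuronal genes of both regions were lower by a mean of -0.65 (SE 0.20), with 8 of 12 called. All 12 belong to the neuronal list, whose fall was known when they were picked. They are therefore no independent test, and that explanation stays open for the neuronal genes. For the ventral genes and for Emx2 and Lhx2 the midbrain list, with a mean of -0.19 (SE 0.09) and a median of -0.07 where that explanation needs a rise, goes against it, but the list was not called (camera adjusted p = 0.131) and includes genes of neurons such as Th (-0.72), so it stays open, as does an effect of YAP, which was not tested.

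In Nf2 knockout, camera called the endothelial and erythroid lists lower and the microglial list higher, but the first pair of calls was lost with an estimated correlation (adjusted p = 0.242 for each), and fry, which tests whether a list moves one way, called neither (0.175 and 0.128). The microglial list was called by both (adjusted p = 0.0474 with an estimated correlation and 0.0499 with fry). For the endothelial genes themselves, with a mean difference of -0.28 (SE 0.14), less vessel carried along and a change in the tissue cannot be told apart from 3 arrays each. Their differences ran from -0.53 for Cldn5 to -0.01 for Kdr. Cldn5 averaged 7.84 in controls and 7.32 in knockouts, and the erythroid gene Hba-a1 13.31 and 13.08. The naming rule picked neither of these genes. Unequal sex of the embryos and a single array might contribute to the endothelial difference and stay open there, since it was -0.24 (SE 0.15) with sex as a covariate and -0.16 (SE 0.11) without knockout replicate 3. Both are argued against as the whole source for the other lists, where the difference with sex as a covariate was -0.23 (SE 0.034) for erythroid and 0.26 (SE 0.033) for microglial genes, and that nearest to 0 with 1 array left out was -0.22 (SE 0.039) and 0.25 (SE 0.033). An effect of Nf2 stays open as untested.

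Among genes that rose in both experiments, more rose further with YAP overexpression than in Nf2 knockout. The Nf2 arrays looked separately normalized, and a compressed scale could make their effects smaller. Their interquartile range averaged 3.81, wider than the 3.49 of the YAP arrays, which by this measure argues against a compressed scale. Rescaling them to 3.49 could therefore only widen the difference and adds no evidence. It gave a median difference of 0.34, against 0.28 before, and a mean difference of 0.41 (SE 0.068 between arrays). Age, tissue, dose of the activity and the heterozygous Nf2 controls differ between the experiments and stay open as untested.

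The following genes differed between the experiments by the test of the difference. The effect on the log2 scale was higher with YAP overexpression by 2.66 for Clu, 2.07 for Apela, 1.47 for Folr1, 1.44 for Pkp2, 1.38 for Dusp3, 1.36 for Atf3, 1.24 for Slc2a3, 0.95 for Adamts9 and 0.92 for Ccn1. It was lower by the signed amounts of -0.71 for Elavl4, -0.71 for Lhx2, -0.84 for Mfng, -0.86 for Cckar, -0.91 for Sstr2, -1.02 for Casq1, -1.21 for Eomes and -1.30 for St18. Some of these genes had a low signal in 1 experiment, where a change may go unseen or be understated. Pkp2 read below the array median on every Nf2 control array, so its rise there may be understated and its difference overstated. With the _x_at and _s_at probe sets left out, Pkp2 was called in neither comparison. On the Nf2 arrays, with medians of 4.3 to 4.42, Apela read 3.20 to 3.47 and Atf3 3.45 to 3.82. On the YAP arrays, with medians of 5.03 to 5.1, Casq1 read 4.73 to 5.10 and Cckar 4.76 to 5.11.

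Probe sets tied to no single gene, which no comparison used, also changed. Of 16139 such probe sets, 482 were called with YAP overexpression, 169 higher and 313 lower, with extremes of 3.06 and -1.86. In Nf2 knockout 16 were called, 13 higher and 3 lower, with extremes of 1.52 and -2.24.

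The 6 arrays of a comparison can be split in only 10 ways, the real one included, too few for a share under 0.05. The real split called 1078 genes for YAP and the highest other 3. For Nf2 the real split called 43 and the highest other 2, or 0 among the splits that also part all 3 same-numbered pairs. For the difference, 100 of 200 joint splits were drawn, and 5, the real one included, gave at least the real 48 genes, the highest other giving 413, so chance is not excluded by this count. The 4 others all kept the real YAP split and so carry the YAP effect, and the highest draw without it gave 2.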

How the results depend on the processing

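Quantile normalization within each experiment and embryo sex as a covariate were chosen only after the results were seen. Where a count changed, the cause was not tested, except that stricter thresholds lower it by construction and all probe sets raise the number of tests.

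The YAP count of 1078 became 446 with a fold of at least 1.5, 375 at an adjusted p under 0.01, 689 with the block, 361 on the 6 arrays and 1704 over all probe sets, and ran from 797 to 1419 in the other settings and from 529 to 1241 with 1 array left out. The 361 and 689 shared 349 and 635 genes with the 1078. The Nf2 count of 43 became 19 at an adjusted p under 0.01, 21 with the block, 25 on the 6 arrays and 67 with array weights, and 20 to 32 with 1 array left out. The 21 and 25 each shared 19 genes with the 43. Differing genes, 48 in number, became 18 at an adjusted p under 0.01, 21 with the block and 129 with trended and robust moderation, and 21 to 161 with 1 array left out. No fit of the 6 arrays alone gives a difference. Genes changed alike in both, 28 in number, became 17 at an adjusted p under 0.01, 15 with the block, 18 on the 6 arrays and 44 with trended and robust moderation, and 15 to 32 with 1 array left out. The correlation of 0.332 (jackknife SE 0.0778) became 0.641 among called genes and 0.415 without the dimmest 40% of genes, and 0.276 to 0.357 with 1 array left out. Normalization within each experiment gave 1059, 36, 55 and 25 genes for YAP, Nf2, the difference and both, and sex as a covariate gave 1023, 32, 43 and 26.

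The YAP/TEAD list in YAP overexpression had an adjusted p of 0.136 with an estimated correlation and 0.000829 with fry. It had 0.135 without Ankrd1, Ccn1 and Ccn2, and 0.000157 to 0.0135 with 1 array left out. In Nf2 knockout it had 0.242, 0.121 with fry, which tests another hypothesis, and 0.453 without the 3 genes, and 0.00917 to 0.0339 with 1 array left out. This list's direction was kept in these settings in both comparisons. Of the 72 called genes named for YAP, 48 kept their call in all settings, 23 lost it in some and Slc2a3 reversed to -0.18 with the _x_at and _s_at probe sets left out. Of 24 named for Nf2, 9 kept it in all and 15 lost it in some. The block ended 9 of the named YAP calls and the call of the Notch list, though the YAP arrays did not look paired, and it ended 24 of the 43 Nf2 calls, 11 of them of genes named by the rule, and no Nf2 list call.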

Other observations

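The genes in the next paragraph were chosen after their values were seen, and no test of an explanation was made for them.

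Genes called in Nf2 knockout and not called with YAP overexpression included Pdpn, which encodes podoplanin (0.59), the growth factor gene Tgfb3 (0.57), the matrix protein gene Vit (0.80), Tlcd4 (0.77) and P3h2, a collagen-modifying hydroxylase gene (0.50), and the difference between the comparisons was called for none of these 5 by limma (adjusted p from 0.0954 to 0.226, all 5 at an unadjusted p under 0.05). With same-numbered Nf2 arrays as a block, Vit and Tlcd4 stayed called, while Pdpn (adjusted p = 0.115), Tgfb3 (0.118) and P3h2 (0.0717) did not. Further genes called higher in both comparisons were Podxl, a sialomucin of apical membranes (1.08 with YAP overexpression and 0.85 in Nf2 knockout), the cadherin gene Cdh6 (1.17 and 0.77), Shroom3, which acts in apical constriction (0.98 and 0.64), Steap2 (0.67 and 0.97), Mfsd2a, a lipid transporter gene (0.70 and 0.80), and the phosphatase genes Ptpn13 (0.47 and 0.56) and Dusp16 (0.69 and 0.45). With the block, Steap2 and Ptpn13 stayed called in Nf2 knockout, while Podxl (adjusted p = 0.0924), Cdh6 (0.0717), Shroom3 (0.0701), Mfsd2a (0.138) and Dusp16 (0.138) did not. Bmp6, which rose with YAP overexpression, was not called in Nf2 knockout (0.72, adjusted p = 0.118), and neither was Rspo2, another gene of the cortical hem list (0.50, adjusted p = 0.115). Clu, the largest rise with YAP overexpression, was not called in Nf2 knockout (0.95, adjusted p = 0.146). Its Nf2 arrays did not overlap, at 9.11 to 9.26 in controls and 9.91 to 10.31 in knockouts. The test's spread is shared with the YAP overexpression arrays, which read 9.35 to 10.38, so the missing call does not show that Clu stayed unchanged.

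The mean of the p53 list was higher than in controls by 0.31 (SE 0.17, n = 3), and the overexpression arrays differed, at 0.19, 0.64 and 0.09 for replicates 1, 2 and 3.

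By Xist and Y-linked transcripts, 1 of 3 YAP overexpression arrays (replicate 3), 1 of 3 YAP control arrays (replicate 2), 1 of 3 Nf2 control arrays (replicate 2) and 2 of 3 Nf2 knockout arrays (replicates 2 and 3) came from female embryos.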
